A study of Mus musculus with 20 samples.

How the data were processed

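RNA sequencing libraries were made from 20 mouse placentas at embryonic day 15.5, 14 labelled knockout and 6 labelled control for Slc11a2, which encodes the divalent metal transporter DMT1. The labels give 8 female and 6 male placentas in the knockout group and 4 female and 2 male placentas in the control group, all of the strain 129S6/SvEvTac. Some sample descriptions carry the prefix RESUB, whose meaning the labels do not give: 8 knockout and 4 control libraries have it, and 6 knockout and 2 control libraries do not. Both male controls have it, so no control library without it is male. The labels do not say that the samples of a group came from separate litters, so p-values measure the spread between these samples. The labels also do not say which part of Slc11a2 was deleted.

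Per the submitters' processing notes, reads passed through bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.2b and featureCounts from Subread 1.5.2, on the genome build GRCm38.p6. Whether reads were counted by strand is not given in the sources used here. The deposited table holds 16058 genes by 20 libraries as a signal that is never negative: gene read counts divided by 1 size factor per library, as the authors' table itself shows. Multiplying each column back gave whole reads in 100% of the values of every library, with a tolerance of 0.001 reads. The recovered factors equalled the median-of-ratios factors that DESeq2 1.42.0 computes on these genes to within 4.66e-13%. Every deposited gene had at least 201 reads summed over the 20 libraries, so low genes had been removed before deposit by a filter that is not stated. Gene identifiers were matched to GENCODE release M21, the same build: 16026 had a symbol, 32 had none, and 16034 had coordinates.

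The recovered reads in genes ranged from 21.38 to 43.43 M per library, with a median of 31.74 M. Control libraries held 30.6 to 34.47 M reads and knockout libraries 21.38 to 43.43 M. A gene at the filter of a mean value of 10 therefore rests on few reads per library, and its fold change on the log2(value + 1) scale is understated. No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom between pairs, over genes with at least 20 reads in the pair, was 11.5 or more, so all 20 were counted as separate samples.

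Before the data were examined, the tests, covariates, gene lists and the rule for named genes were fixed. The genotype effect was fitted with limma 3.58.1 (R 4.3.3) on log2(value + 1) of the deposited values, with a trend in the variance, for 16024 genes with a mean value of at least 10. Sex and the prefix entered as terms, since both are spread unevenly over the genotypes. Effects in females and males and their difference came from a mean per genotype and sex, with the prefix as a term. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The same model gave the sex effect. The difference between libraries without and with the prefix, from the same model, was taken up only after the data were seen.

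The named genes are Slc11a2, then among genes past the threshold with a mean of at least 50 and a symbol that is not a predicted name the 12 with the largest change in each direction. Where fewer than 5 passed in a direction, the 5 with the smallest p in it are given. Up to 4 members with the smallest p are named for each gene list, with Xist and 4 Y-linked genes for the sex effect and the 5 genes with the smallest p for the effects in females, in males and their difference. Called genes with predicted names, Gbp11, Rplp0 and its pseudogenes were added after their values were seen. The 27 gene lists are 15 pathway lists and 12 sets of cell type markers, tested with limma's camera at its preset correlation of 0.01, two-sided, with adjustment over the 27 lists. Camera with an estimated correlation and fry were run as alternatives.

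On data simulated from the genes and spread of these libraries, the genotype effect recovered 38% of genes changed 1.25-fold, 66% at 1.5-fold, 84% at 2-fold and 100% at 4-fold, over 16024 genes. It called 6 of 15824 unchanged genes beside them and none when no gene was changed. In females it recovered 54% of genes changed 1.5-fold and in males 38%. Where genes were changed in females alone, the difference between the sexes recovered 0% at 1.25-fold, 20% at 1.5-fold, 64% at 2-fold and 84% at 4-fold. In each simulation the genes were drawn independently of each other, with no prefix effect and no sex effect of their own. The recovery and false call rates may therefore look better than those in the real libraries. Copies of the called genes were searched with BLAST+ 2.17.0 among the GENCODE transcripts, at an identity of at least 95% over at least 100 bases.

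The alternatives were other pseudocounts, filters and scalings, other covariates, each kind of label prefix alone, the replicate number as a block, array weights, robust variance, edgeR 4.0.16 and DESeq2 on the recovered reads, marker covariates, and each library left out in turn. Those added after seeing the data were the omission of chromosome 5 genes, the omission of 5 libraries with an Afp value above 10000, the yolk sac marker mean as a term, and all alternatives of the prefix difference, including a loess correction on transcript length and GC content. No column of the table was left out.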

Results

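Gene expression was measured by RNA sequencing in 20 mouse placentas at embryonic day 15.5, of which 14 were labelled knockout for Slc11a2 and 6 control. Slc11a2 encodes DMT1, a transporter that carries ferrous iron and other divalent metals across membranes. The series compares placentas that differ in this gene. Values are normalised read counts, and each library rests on 21.38 to 43.43 M reads in genes.

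Slc11a2 (ENSMUSG00000023030, GRCm38 chromosome 15, 100387898 to 100425072) was not lower in the libraries labelled knockout. Its normalised read count was 2144 ± 252.8 (SD, n = 14) in them and 1901 ± 169.3 (SD, n = 6) in the control libraries. The ranges overlapped, at 1715 to 2705 and 1687 to 2171. The limma log2 fold change was 0.15 ± 0.06 (SE), with a 95% interval of 0.02 to 0.27 and an adjusted p of 0.42. Among libraries without the prefix the means were 2347 and 2033, and among those with it 1991 and 1835, for knockout and control. One value per gene holds no level per exon and cannot show whether part of the transcript was missing. Because the target gives no support to the labels, the groups are called libraries labelled knockout and control libraries, and every direction below is the first against the second by label.

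Ubc, which encodes a polyubiquitin precursor, was 5.95-fold higher in libraries labelled knockout, and no value of one group reached the other. Its normalised read count was 4998 ± 825 (SD, n = 14) against 861 ± 158 (SD, n = 6), and every library labelled knockout was at 4035 or more while every control library was at 1124 or less. The other ubiquitin genes gave no such difference: the log2 fold change was -0.08 ± 0.06 (SE) for Ubb, -0.00 ± 0.09 for Uba52 and -0.06 ± 0.05 for Rps27a, none past the threshold. In the Ubc transcript 318 bases were identical to the annotated gene Gm10382, which is absent from the deposited table, and how reads in these bases were counted is not known.

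**Figure D1:**
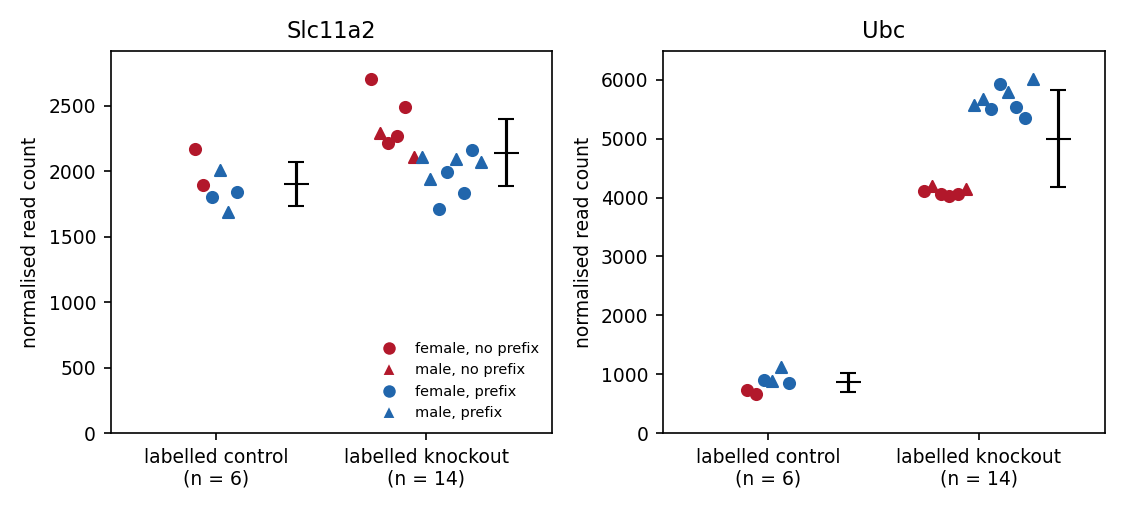
Normalised read counts of Slc11a2 and Ubc in each of the 20 placentas by genotype label, with bars for the mean ± SD of 6 control and 14 knockout libraries, colours for the sample label prefix and shapes for sex. Slc11a2 overlaps between the labels, while the lowest Ubc value of the knockout label, 4035, lies above the highest control value, 1124.

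With Ubc, 13 of 16024 genes passed an adjusted p of 0.05 in limma, 8 higher and 5 lower in libraries labelled knockout. Among the named genes, Zfp605, a zinc finger gene, rose by 0.73 ± 0.13 on the log2 scale (SE, adjusted p = 0.025). Creld2, a gene of the endoplasmic reticulum stress response on chromosome 15, where Slc11a2 also lies, rose by 0.32 ± 0.06 (adjusted p = 0.0462). Aacs, the cytosolic acetoacetyl-CoA synthetase, rose by 0.29 ± 0.05 (adjusted p = 0.0281), and Arpc1a, a subunit of the Arp2/3 actin complex, by 0.18 ± 0.03 (adjusted p = 0.0316). Tctn2, a gene of the ciliary transition zone, fell by 0.55 ± 0.07 (adjusted p = 4.80e-04). Vps37b, a subunit of the ESCRT-I sorting complex, fell by 0.40 ± 0.07 (adjusted p = 0.0316), and Pkd2, the polycystin-2 cation channel, fell by 0.33 ± 0.05 (adjusted p = 0.0155). Over 39 other settings and left-out libraries the call was lost in 25 for Creld2, 20 for Arpc1a, 17 for Vps37b, 12 for Aacs, 9 for Zfp605, 6 for Pkd2, 2 for Tctn2 and 0 for Ubc. Vps37b shares 918 bases with transcripts of Hip1r, so its value is uncertain if reads were counted without strand. Shorter matches were found for Tctn2, with Mfsd4a at 95.1% over 142 bases, and for Arpc1a, with Cenpw at 95.6% over 135 bases.

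The genes with predicted names or low values, chosen after their values were seen, were Gbp11 at 1.80 ± 0.29, 4930515G01Rik at 1.29 ± 0.23, 6430571L13Rik at 0.42 ± 0.07, Gm8730 at -0.60 ± 0.06 and Gm9625 at -0.69 ± 0.09 (log2 ± SE). 4930515G01Rik shares 307 identical bases with Ankrd13a, and Gbp11 aligns with Gbp10 at 95% over 363 bases, so both values are uncertain. Cpt1a, the carnitine palmitoyltransferase of mitochondrial fatty acid import, and Atp10d, a phospholipid flippase gene annotated as a polymorphic pseudogene, are next by p among lower genes. Their log2 values were -0.34 ± 0.07 (adjusted p = 0.112) and -0.77 ± 0.17 (adjusted p = 0.117), short of the threshold. At an unadjusted p of 0.05, 1593 genes differed, 9.94% of those tested. edgeR on the recovered reads called 12 genes, all among the 13, and DESeq2 called 66, of which 11 were among the 13. Libraries without the prefix alone called 272 genes and libraries with it alone called 1, which was Ubc. Of the 272, 5 were among the 13 and 128 had the same sign in libraries with the prefix, and the genotype effects of the 2 sets correlated at 0.023 across genes.

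Of the 13 genes, 9 lie on chromosome 5, between 104.459 and 145.084 Mb: Pkd2, Gbp11, Zfp605, 4930515G01Rik, Vps37b, Tctn2, Ubc, Aacs and Arpc1a. Chromosome 5 held 1023 of the tested genes (Fisher's exact p = 9.64e-09, two-sided, tested after the position was seen). An unadjusted p under 0.01 was found for 68 of these genes, 6.65%, and for 370 of the 15001 other genes, 2.47%. The share was 8.71% of 574 genes between 100 and 150 Mb and 4.01% of 449 genes on the rest of the chromosome. That window was chosen after the called genes were seen and counts them, and it was not uniform: between 130 and 140 Mb only 2 of 139 genes had such a p. Rplp0, a ribosomal stalk gene on chromosome 5, had a log2 fold change of 0.33 ± 0.07 (SE, adjusted p = 0.0659), while Gm8730 on chromosome 8 and Gm9625 on chromosome 13, processed pseudogenes 98.7% and 97.4% identical to it, both fell. With chromosome 5 left out, 2 genes passed, Gm8730 and Gm9625.

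**Figure D2:**
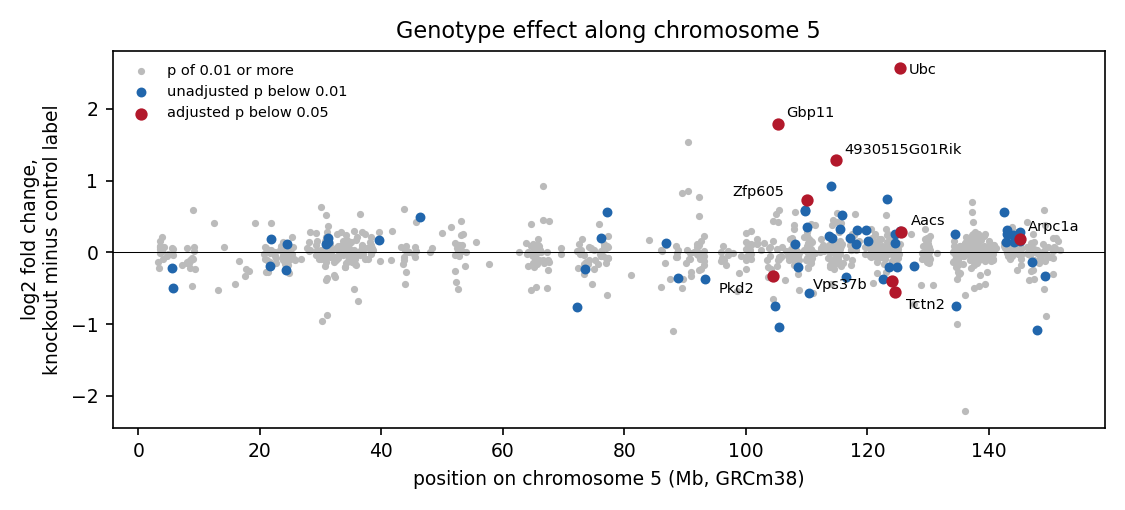
Log2 fold change of the 1023 tested genes of chromosome 5, libraries labelled knockout minus control, against gene start in Mb on GRCm38, with colours for the p-value. The 9 genes past an adjusted p of 0.05 lie between 104.459 and 145.084 Mb.

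Nutrient transporters of the labyrinth, the exchange zone of the placenta, were lower as a group in libraries labelled knockout, with 33 of 37 members below 0 (camera adjusted p = 7.23e-07, but adjusted p = 0.336 with an estimated correlation). The phosphate transporter Slc20a2 was at -0.34 ± 0.11 (log2 ± SE), the organic cation transporters Slc22a4 and Slc22a3 at -0.38 ± 0.13 and -0.26 ± 0.09, and the fatty acid transporter Cd36 at -0.24 ± 0.08. Cd36 lies on chromosome 5, at 17.78 Mb. Targets of hypoxia-inducible factors were also lower, 36 of 43 (adjusted p = 5.05e-04, but 0.336 with an estimated correlation). Their lowest p-values belonged to the glycolytic gene Pgam1 at -0.16 ± 0.06, the glucose transporter Slc2a1 at -0.29 ± 0.11, Ndrg1 at -0.20 ± 0.08 and Pfkfb3, a regulator of glycolysis, at -0.25 ± 0.10. Cholesterol synthesis genes were lower in 18 of 24 (adjusted p = 0.0127, but 0.585 with an estimated correlation), with Msmo1 at -0.21 ± 0.06, Dhcr24 at -0.18 ± 0.07, Pmvk at -0.16 ± 0.08 and Idi1 at -0.27 ± 0.13. No member of these 3 lists passed the threshold over all genes or adjusted over the list alone.

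Cell cycle genes were higher as a group, 34 of 38 above 0 (camera adjusted p = 7.96e-05, but adjusted p = 0.831 with an estimated correlation). Cdc20 was at 0.33 ± 0.10 (log2 ± SE), Bub1b at 0.41 ± 0.15, Cdc6 at 0.36 ± 0.14 and Cenpe at 0.37 ± 0.16, and none passed adjusted over the list alone. The integrated stress and unfolded protein response list was higher in 21 of 36 members (adjusted p = 0.0037, but 0.336 with an estimated correlation), and 9 members rose adjusted over the list alone. These included Creld2, the chaperone Hyou1 at 0.20 ± 0.05, Sdf2l1 at 0.35 ± 0.10, also of the endoplasmic reticulum, and the mitochondrial folate enzyme Shmt2 at 0.17 ± 0.05. Only Creld2 passed over all genes.

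Iron genes did not pass as a group (camera adjusted p = 0.504). Of the uptake, storage and export list 17 members were above 0 and 22 below, and none passed adjusted over the list alone. An unadjusted p under 0.05 was found for 9 of the 39, against 9.94% of all genes tested. Camera tests for a shift in 1 direction, so mixed changes are not excluded. Tfrc, the transferrin receptor, was at 69680 against 55460, a log2 fold change of 0.37 ± 0.11 (SE), and had an adjusted p of 0.0743 over this list. The ferrireductases Cybrd1 and Steap2 were at -0.39 ± 0.12 and -0.50 ± 0.16, and Ncoa4, the ferritin receptor of autophagy, at -0.16 ± 0.06. Of these, Steap2 lies on chromosome 5, at 5.66 Mb. In heme synthesis Abcb10 was at -0.15 ± 0.05 and Alad at 0.13 ± 0.05 (camera adjusted p = 0.615). Iron-sulfur cluster genes had 0 of 34 members with an unadjusted p under 0.05 (camera adjusted p = 0.658). Oxidative phosphorylation had 0 of 48 (camera adjusted p = 0.995), but lay at a mean log2 of -0.18 among libraries without the prefix and 0.10 among those with it. In those 2 sets the genotype effect also ran with transcript length across 15992 genes, with Spearman's rho of 0.21 and -0.18 (genes are not independent replicates).

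In the oxidative stress and ferroptosis list Srxn1 (sulfiredoxin), Tfrc and Txnrd1 (thioredoxin reductase) rose and Aifm2, which encodes the ferroptosis suppressor FSP1, fell adjusted over the list alone, at 0.36 ± 0.09, 0.37 ± 0.11, 0.15 ± 0.05 and -0.25 ± 0.08 (log2 ± SE). None of the 4 passed over all genes, and the list did not (camera adjusted p = 0.988). Handling of zinc, copper and manganese (0.960), the interferon response (0.171), the inflammatory response (0.984), angiogenic and placental growth factors (0.171) and imprinted genes (0.744) did not pass either, by camera adjusted p. The zinc transporters Slc30a2 and Slc39a4 were at 0.27 ± 0.08 and -0.42 ± 0.18, Mx2 at 0.60 ± 0.21, Nfkbia at -0.21 ± 0.10, Igf1 at -0.67 ± 0.23 and Kcnq1ot1 at 0.42 ± 0.17. For oxidative phosphorylation the test leaned down while the mean was 0.00269. For the oxidative stress, inflammatory and erythroid lists the median was below 0 and the mean above it, and for the metal list the reverse.

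**Figure D3:**
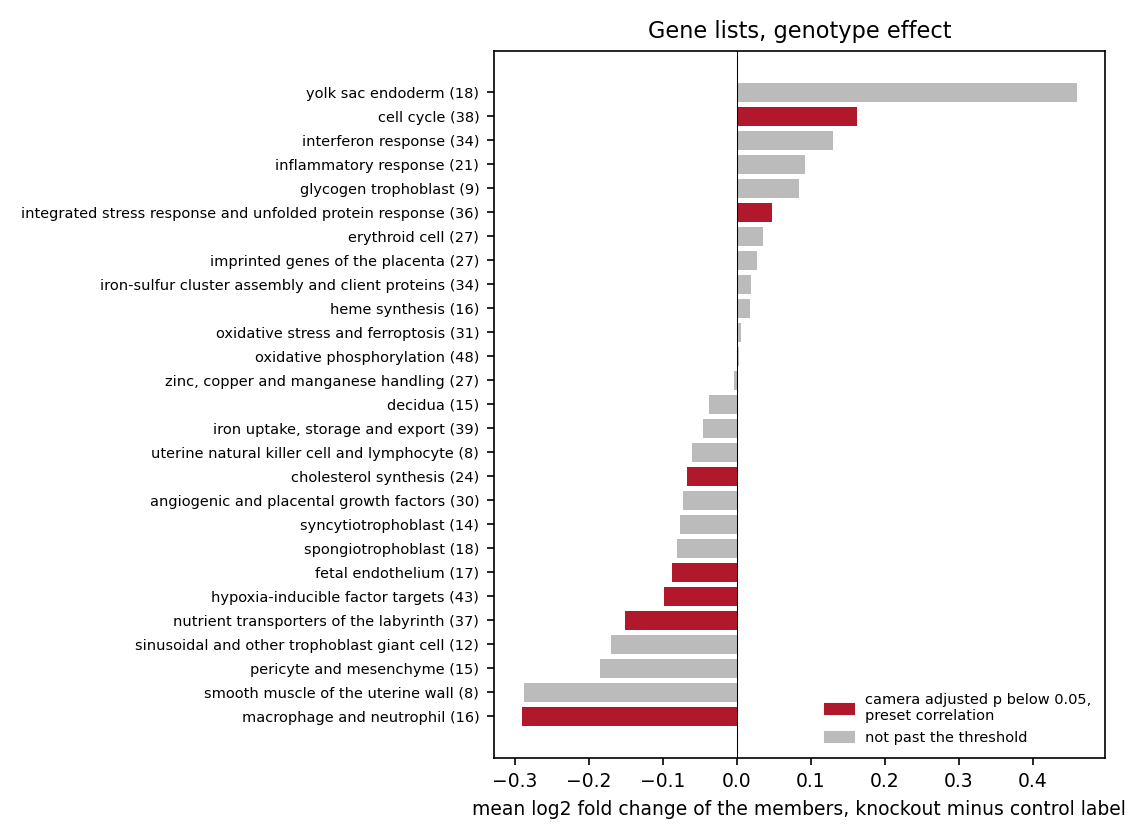
Mean log2 fold change of the members of each of the 27 lists, libraries labelled knockout minus control, with the number of members in parentheses; red bars passed a camera adjusted p of 0.05 at the preset correlation of 0.01. The 7 red bars include nutrient transporters at -0.15 and the cell cycle at 0.16, and none of them passed with an estimated correlation.

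Among cell type markers, macrophage and neutrophil genes were lower as a group, 15 of 16 below 0 (camera adjusted p = 8.66e-06, but adjusted p = 0.206 with an estimated correlation). The complement genes C1qb, C1qa and C1qc were at -0.31 ± 0.11, -0.33 ± 0.11 and -0.29 ± 0.11 (log2 ± SE), and the lysozyme gene Lyz2 at -0.44 ± 0.16. Fetal endothelium markers were lower in 14 of 17 (camera adjusted p = 0.0261, but 0.831 with an estimated correlation), with Nos3, on chromosome 5 at 24.3648 Mb, at -0.25 ± 0.08, Pecam1 at -0.16 ± 0.07, Tek at -0.12 ± 0.07 and Tie1 at -0.13 ± 0.08. The alternative test fry gave an adjusted p of 0.0432 for the macrophage list and 0.612 for endothelium. Over 38 other settings and left-out libraries the endothelial call was lost in 16, the omission of chromosome 5 among them, and the macrophage call in 1. No member of either list passed adjusted over the list alone.

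The other marker sets did not pass. The syncytiotrophoblast list had 2 members past the threshold adjusted over the list alone: Syna (syncytin A) whose gene lies on chromosome 5 at 134.558 Mb, fell by 0.75 ± 0.21 on the log2 scale, from 6147 to 3580, and Tfrc rose by 0.37 ± 0.11 (SE; camera adjusted p of the list 0.472). Smtn rose by 0.19 ± 0.05 in the list of uterine smooth muscle, whose other 7 members were below 0 (0.622). The camera adjusted p was 0.744 for erythroid cells, with Hbb-bh1 at 0.51 ± 0.21, 0.472 for sinusoidal and other giant cells, with Hand1 at 0.20 ± 0.07, and 0.713 for spongiotrophoblast, with Prl8a6 at -0.71 ± 0.28. It was 0.658 for glycogen trophoblast (Gjb3 at 0.07 ± 0.04), 0.718 for decidua (Angptl2 at -0.29 ± 0.17), 0.988 for uterine natural killer cells and lymphocytes (Ptprcap at 0.26 ± 0.27) and 0.472 for pericytes and mesenchyme (Rgs5 at 0.35 ± 0.15). Yolk sac endoderm markers did not pass either (0.285). Their member Afp (alpha-fetoprotein) ranged from 317.5 to 109900, and 5 libraries exceeded 10000, knockout replicates 2, 8 and 10 and control replicates 1 and 6. Without those 5 libraries 5 genes passed over all genes in place of 13. Leaving out knockout replicate 11 alone gave 6, so the smaller number of libraries was not told apart from yolk sac content.

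In female placentas, 8 labelled knockout and 4 control, 3 genes passed: Ubc at 2.60 ± 0.06 (log2 ± SE), and Gm8730 and Gm9625, both lower. Tctn2 was at -0.49 ± 0.09 (adjusted p = 0.0625), Upf1, a factor of nonsense-mediated decay, at 0.52 ± 0.09 (0.0646), Pkd2 at -0.34 ± 0.07 (0.187) and Disp2 at -0.74 ± 0.15 (0.189). In male placentas, 6 and 2, Ubc alone passed at 2.52 ± 0.08. Both male controls carried the prefix and 2 males labelled knockout did not. The effect in males thus assumes that the prefix acts alike in both genotypes and sexes. Tctn2 was at -0.67 ± 0.12 (0.102), Bri3bp at 0.41 ± 0.10, and the interferon-induced genes Ifit2 and Mx1 at 1.58 ± 0.42 and 2.74 ± 0.75. Of the 2 male controls, replicate 4 had the lowest interferon response of all controls, a mean log2 of 8.206 against 9.046 for the next. By limma no gene differed in its genotype effect between the sexes, and edgeR called 0. An unadjusted p under 0.05 was found for 434 genes, 2.71% of those tested. That is a smaller share than this threshold gives where no gene differs. The smallest p-values of that difference, female minus male, belonged to Ambp at -5.20 ± 1.56, Igfbp1 at -2.83 ± 0.86, Atp6v0a4 at -1.08 ± 0.33, S100a14 at -1.09 ± 0.33 and Mx1 at -3.04 ± 0.93, all with an adjusted p of 1.

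The sex labels were met by every library. Xist, the RNA of the inactive X chromosome, was at 2121 ± 814.2 (SD, n = 12) in females and 179.1 ± 40.83 (SD, n = 8) in males, a log2 difference of 3.46 ± 0.23 (SE). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were lower in females by limma, at -7.83 ± 0.47, -7.19 ± 0.34, -6.05 ± 0.31 and -7.31 ± 0.29. Males held 1506 ± 255.5 (SD, n = 8) of Ddx3y and females 7.16 ± 5.79 (SD, n = 12). In all, 10 genes passed, 6 higher in females: Xist, Eif2s3x, Kdm5c, Taf1, 5530601H04Rik and an unnamed gene, ENSMUSG00000051412, chosen here after their values were seen. As groups, heme synthesis (2 of 16 above 0), oxidative phosphorylation, oxidative stress, cell cycle, cholesterol synthesis, erythroid, glycogen trophoblast and yolk sac genes were lower in females and spongiotrophoblast genes higher by camera, and the adjusted p of each was 0.831 with an estimated correlation.

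The prefix in the sample descriptions separated libraries far more than genotype did. The libraries without it held more embryonic globin RNA: Hbb-y was at 8958 ± 4391 (SD, n = 8) against 620 ± 474.1 (SD, n = 12), 15.3-fold on the log2(value + 1) scale (adjusted p = 1.12e-07), Hba-x was 5.74-fold and Hbb-bh1 3.31-fold higher. Cell cycle genes rose together, 34 of 38 over all genes, among them Bub1b at 3.95-fold and Ccna2 at 3.84-fold (camera adjusted p = 2.81e-16, and 0.531 with an estimated correlation). Markers of sinusoidal and other giant cells did not pass as a group, with 4 of 12 higher and 6 lower over all genes (camera adjusted p = 0.232, and 0.910 with an estimated correlation). Those with the smallest p fell: the cathepsin Ctsq at 0.291-fold, Ctsj at 0.426-fold, Lepr at 0.489-fold and Prl3b1, a placental lactogen, at 0.539-fold. Among nutrient transporters 23 of 37 fell and 5 rose over all genes, with Slc7a8 at 0.334-fold and Fabp3 at 0.496-fold and Slc22a5, a carnitine transporter, higher by 0.68 on the log2 scale (camera adjusted p = 0.00552, and 0.910 with an estimated correlation).

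Cholesterol synthesis rose, 15 of 24 higher and 1 lower over all genes, with Sqle at 1.44-fold (camera adjusted p = 0.0011, and 0.531 with an estimated correlation). Endothelial markers fell, 11 of 17 lower and 2 higher over all genes, with Plvap at 0.5997-fold (camera adjusted p = 0.0401, and 0.910 with an estimated correlation). Of the uterine natural killer cell and lymphocyte genes 6 of 8 rose over all genes, with Prf1 (perforin) at 6.69-fold and Gzmd at 3.66-fold, but the list did not pass (camera adjusted p = 0.0633). Of the glycogen trophoblast genes 7 rose and 2 fell, with Prl7b1 at 4.56-fold and Igfbp7 at 0.510-fold, and that list did not pass either (0.0633). Of the decidual genes 8 rose and 3 fell, with Dio3 at 6.17-fold, Prl8a2 at 4.20-fold, Cited1 at 0.615-fold and Wnt4 at 0.491-fold (0.245). With an estimated correlation the adjusted p of each of these 3 lists was 0.910. In all, 9158 of 16024 genes passed by limma, 4573 higher and 4585 lower without the prefix. The first principal component carried 38.5% of the variance. Its libraries without the prefix lay between -57.4 and -32.6 and the others between 4.39 and 48.1.

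**Figure D4:**
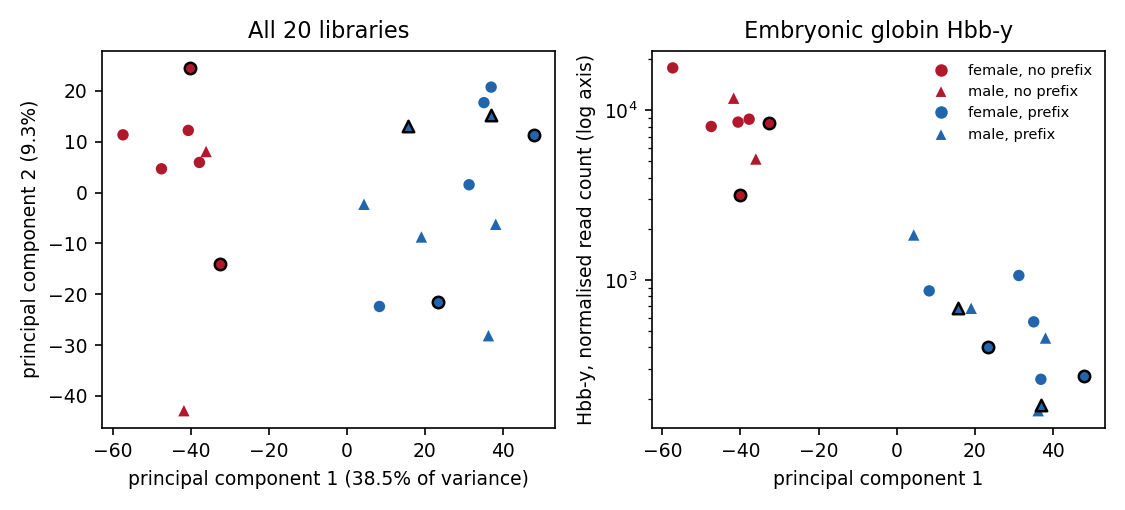
Left, the first 2 principal components of log2 values of the 20 libraries; right, the normalised read count of Hbb-y on a log axis against the first component. Colours give the label prefix, shapes the sex and black outlines the 6 control libraries; libraries without the prefix lie at -32.6 or below on the first component, those with it at 4.39 or above.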

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

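The tests on chromosome 5, Rplp0, the prefix, the Ubc ranges and the whole Slc11a2 transcript were chosen only after the results were seen. In each set of 100 splits, the real grouping is included.

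Of the 13 genes that passed between the genotype labels, 9 lie on chromosome 5, whereas Slc11a2 lies on chromosome 15. Creld2, another of the 13, lies on chromosome 15 too, from 88819646 to 88826683, and Slc11a2 from 100387898 to 100425072. Whether the change of Creld2 goes with its position was not tested. A response to the loss of Slc11a2 stays open for these 9 genes, since the Fisher's exact p of 9.64e-09 restates the position that prompted it and decides nothing. A stretch of chromosome 5 of another strain origin could give such a pattern: among genes that did not pass, a p under 0.01 was more frequent on chromosome 5 (odds ratio 2.469, 95% interval 1.83 to 3.29). That interval takes genes as independent, though all were measured in the same libraries, so it can be too narrow. Only 2 of 100 splits gave as high a ratio, but the highest other split gave 2.94, and without sequence variants the data do not decide this. For Gm8730 and Gm9625 off that chromosome, reads shared with Rplp0 may account for the fall. The lower bound of the limma log2 change of Rplp0 was 0.1936, in the opposite direction. The sum of the 3 genes rose by 0.159 (95% interval 0.0274 to 0.29). Reads moved only among these 3 would leave the sum unchanged. But the copy search matched Rplp0 to 4 genes, which include Gm8730 and Gm9625, so some matches lie outside the sum. How shared reads were counted is not given either, so the sum does not decide this.

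Slc11a2 was not lower in libraries labelled knockout. By the labels given, the lower bound of the log2 change was 0.02351, which argues against loss of the whole transcript. Swapped labels would not alter this: Slc11a2 was at 1687 to 2171 in control libraries and 1715 to 2705 in those labelled knockout. No library lacked it, so no exchange of labels gives a group without the transcript. Whether any labels were swapped is a separate question that stays open. For it, 0 libraries had a Ubc value inside the range of the other group. But Ubc was picked for parting the groups and lies on another chromosome than Slc11a2. A deletion of part of the gene that leaves a counted transcript could give a fold change of 1.107, and the data hold no level per exon to test it. No biological explanation beyond the label was tested.

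Libraries without and with the prefix differed in 9158 genes. An earlier gestational stage of the libraries without it could account for part of this, though all are labelled embryonic day 15.5. The median log2 difference of the embryonic globins exceeded that of the other erythroid markers by 2.613. But these globins were set apart after their difference was seen, so the value restates it and does not decide on stage. A bias by GC content or transcript length is not a sufficient account of most of it: 8776 genes passed after a correction for both, of which 7306 were among the 9158, so which genes pass depends in part on that correction. A difference between sequencing or library batches may also be present, since 0.906 of the variance of the first principal component goes with the prefix, but the labels give no batch and the data do not separate it from stage.

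Each set of splits reassigned at random the label under test, and the other labels stayed with each library: the genotype label over all libraries, the genotype label of the female libraries for the effect in females, the sex label, or the prefix. In 3 of 100 splits of the genotype label the count of genes reached 13, with 122 in the highest other split. What gave that count was not tested. For the effect in females it was 1 of 100, with 0 genes in the highest other split, for the sex effect 3 of 100, with 52, and for the prefix 1 of 100, with 3734. For these 4 results chance alone is an improbable source, at the resolution of 100 splits. For the gene lists 31 of 100 splits gave at least 5 lists, up to 7, and for the markers 89 of 100 gave at least 2, up to 8, so for both chance cannot be excluded.

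Of 82 sets of samples tested for a library far from the rest, 9 had one. The cutoff gives about 1 in 20 for independent, normally spread values. But gene values were tested unlogged, and some genes were picked for small p-values, which a far library can help to give. The 9 are therefore not read as an excess over chance. Control replicate 2 had the lowest mean log2 of zinc, copper and manganese genes, 10.13 against 10.24 for the next control. Control replicate 4 had the lowest interferon response, 8.206 against 9.046, and the lowest inflammatory response, 6.453 against 7.156. Knockout replicate 6 had the lowest Mx1 among males labelled knockout, 41.32 against 124.3. Ambp was highest in knockout replicate 10 among females labelled knockout, 129.5 against 25.59. Among males labelled knockout it was highest in replicate 2, 662.5 against 138.1. Both libraries had an Afp value above 10000. Igfbp1 was highest in knockout replicate 9 among females, 306.8 against 110.1, and in knockout replicate 8 among males, 727.8 against 244.5. Atp6v0a4 was lowest in knockout replicate 4 among females, 62.21 against 123.1.

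The genotype effect differed between libraries without and with the prefix for 9 genes: Crocc, Golgb1, Numa1, Cep250, Zc3h18, Zfc3h1, Golga2, Golga4 and Tpr (limma adjusted p = 0.0408 for each). Crocc was at 168.7 in the 2 control libraries without the prefix and 381.4 in the 6 labelled knockout without it. With the prefix it was at 377.2 in control libraries and 390.1 in those labelled knockout. Each of the 9 genes was higher in libraries labelled knockout among those without the prefix, where the control side rests on 2 libraries. Across genes the genotype effect also ran with transcript length, with Spearman's rho of 0.21 without the prefix and -0.18 with it. Whether this trend accounts for the 9 genes was not tested. By camera, the difference in genotype effect without minus with the prefix was -0.125 for iron-sulfur cluster genes, -0.282 for oxidative phosphorylation, -0.164 for oxidative stress and ferroptosis and -0.145 for nutrient transporters, in mean log2. None of these 4 passed with an estimated correlation, where the adjusted p was 0.653, 0.627, 0.653 and 0.867.

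The genotype effect also differed between the sexes for 9 lists by camera, given as female minus male in mean log2, but with an estimated correlation the inflammatory response alone passed (adjusted p = 0.0336). It was -0.301 for iron uptake, storage and export, -0.085 for targets of hypoxia-inducible factors, -0.196 for nutrient transporters and 0.2 for the cell cycle. It was -0.553 for the interferon response, -0.757 for the inflammatory response, -0.27 for erythroid, -0.204 for macrophage and neutrophil and -3.7 for yolk sac endoderm genes. The male side rests on 2 control libraries, both with the prefix, while 2 males labelled knockout lack it. The difference between the sexes thus assumes that the prefix acts alike in both genotypes and sexes. Control replicate 4, a male, held the lowest inflammatory value of the controls.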

How the results depend on the processing

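Another setting than the chosen one left 275 values of named genes on their side of the threshold, made 57 weaker and 6 stronger and reversed 0; for lists these were 449, 25, 10 and 2. Leaving out a library left 282 gene and 521 list values, made 74 and 9 weaker and 4 and 9 stronger, and reversed 1 list. Among the alternatives, the omission of chromosome 5, of the Afp libraries, the yolk sac term and those of the prefix difference were chosen after seeing the data. Among genes with predicted names or low values the call was lost in 20 of 37 alternatives for 4930515G01Rik, 4 of 37 for Gbp11, 12 of 39 for 6430571L13Rik and 2 of 39 for Gm8730 and for Gm9625. Among pathway lists it was lost in 6 of 38 for cholesterol synthesis, 5 for the stress response and 2 each for the cell cycle, hypoxia targets and transporters. Depth limits the genes of low value, such as Gbp11. Where no reason is given below, the cause was not tested.

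Libraries without the prefix alone gave 272 genes for genotype and a mean log2 of -0.134 for oxidative stress genes, turned in sign. Libraries with it alone gave 1 gene, 9 pathway lists and 0.1018 for oxidative phosphorylation. Quantile normalization gave 5 genes in females, and DESeq2 gave 66 for genotype. Array weights left 1 marker list. Camera with an estimated correlation left 0 pathway and 0 marker lists, and fry 0 and 1. The yolk sac term left 1 marker list. Without the 5 libraries high in Afp 5 genes passed. Without chromosome 5, which holds most called genes, 2 genes and 1 marker list passed. Control libraries alone gave 1935 genes for the prefix.

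With the replicate number as a block, 2 genes passed for genotype, 1 marker list, 0 genes in females, 0 in males and 4 for sex, with 3 residual degrees of freedom. The values gave no sign that the numbers pair the samples. Deviations of same-numbered libraries from the genotype means correlated at -0.479 to 0.404, but these leave the prefix in. With prefix and sex also fitted, the correlations were -0.268 to 0.14.

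Leaving out each library in turn gave 6 to 19 genes for genotype, 2 to 7 in females, 1 to 5 in males, 0 to 2 for the difference between sexes, 8 to 11 for sex, 5 to 7 pathway lists and 1 to 3 marker lists. For genotype, 8 passed without control replicate 1 or 3 or knockout replicate 2, 10 or 12, 7 without control replicate 4 or 5 or knockout replicate 13, and 6 without knockout replicate 11. In females 7 passed without knockout replicate 9 and 6 without knockout replicate 2 or control replicate 6. In males 5 passed without control replicate 5, leaving 1 male control assumed to vary like the others, and 2 without control replicate 3 or 6. The difference between sexes gave 2 without control replicate 5. Marker lists fell to 1, with fetal endothelium lost, without knockout replicate 4, 7, 8, 10 or 12 or control replicate 3 or 4. The mean log2 of oxidative phosphorylation ran from -0.03082 to 0.04457, the latter without control replicate 1 with an adjusted p of 0.0196.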

Other observations

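Genes of stratified epithelium varied between single libraries, and were looked at only after their values were seen. Krt5, a basal keratin, was at 214.3, 449.7, 235.6 and 135.5 in control replicates 1, 2, 5 and 6 and at 5.38 and 3.90 in control replicates 3 and 4. Among libraries labelled knockout it was at 73.5 in replicate 9, 49.07 in replicate 14 and 12.23 or less in the others. The log2 fold change was -3.06 ± 0.89 (SE, limma adjusted p = 0.309). Lypd3 was at -1.83 ± 0.50 (adjusted p = 0.273) and Muc16 at -2.23 ± 1.10 (0.516), with a Muc16 of 128.9 in knockout replicate 9 and 94.24 in control replicate 6.

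As a hypothesis formed after the prefix difference was seen, libraries labelled knockout might resemble an earlier stage, with a genotype effect that runs along the prefix effect across genes. The correlation was 0.131, and 55 of 100 splits of the genotype label, the real one included, gave one as large in size, down to -0.633. The test gave the hypothesis no support.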
